A study of Homo sapiens with 20 samples.

How the data were processed

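Total RNA from B5/589 cells, an immortalized human mammary epithelial line carrying a doxycycline-inducible p53 transgene, was biotin-labelled and hybridised to 20 Affymetrix arrays. Each array held 1 sample. The labels give 5 groups of 4 arrays, namely 0 ng of doxycycline for 24 h, 3 ng for 12 h, 5 ng for 12 h, 3 ng for 24 h and 5 ng for 24 h. They give the doses as ng with no volume, and uninduced cells at 24 h only. Nothing in the labels says whether the 4 arrays of a group came from separate cultures, so every p-value measures the spread between these samples, which may be technical. The number of arrays limits the precision.

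The deposited values are signals on the log2 scale, with 1 value per transcript cluster (the probes of 1 transcription unit) and array. GCOS, GCRMA, Affymetrix Power Tools and limma are named, without versions, roles or order, in the submitters' processing notes. Which step scaled the arrays to one another is not given in the sources used here. The arrays differed in brightness as deposited, with array medians from 4.54 to 5.54. The values were used as deposited, with no further scaling, and the results after quantile normalization between arrays are printed beside them.

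The deposited values covered 33297 transcript clusters. Of these, 19460 had 1 gene symbol in the platform annotation used here, 1754 had several and 12083 were not listed in it. Entrez identifiers matched 19429 of the clusters with 1 symbol to current gene records, and 0 symbols changed. Genes were named only from clusters with 1 symbol, and the cluster with the highest mean stood for each of the 769 genes that had more than 1. This left 18417 genes, and none was filtered out for low signal. A planned result and its alternatives were not run and are not reported here, and list members without a named cluster are not analysed here.

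A linear model with 1 mean for each of the 5 groups was fitted to all 20 arrays in limma 3.58.1 under R 4.3.3, which leaves 15 residual degrees of freedom, and standard errors were moderated with eBayes. The comparisons were 3 ng and 5 ng against 0 ng at 24 h, 5 ng against 3 ng at 24 h and at 12 h, each 12 h group against 0 ng at 24 h, 24 h against 12 h at each dose, and the interaction of dose and time. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values are log2 differences with the standard error (SE) of the model, over 4 arrays in each group. A count of genes whose groups of 4 arrays did not overlap is set against the 2.86% that chance gives.

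The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names a panel of 14 p53-related genes whether or not they pass, of which 12 had a named cluster. It also names the 10 largest rises and falls past the threshold with groups that did not overlap, and up to 4 members of each list with the largest change past the threshold. For the interaction it names the 5 largest values of each sign. The text gives those that describe each group best.

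There were 20 gene lists. They covered p53 targets in 4 lists (cell cycle arrest, apoptosis, feedback regulators, and repair and metabolism), G2 and M phase genes, S phase genes, replication-dependent histones, BCL2 family members outside the p53 lists, caspases and their inhibitors, and the unfolded protein and integrated stress response. The others were interferon-stimulated genes, NF-kB targets, cholesterol synthesis, immediate early and MAPK feedback genes, ribosome biogenesis, basal, luminal, mesenchymal, and immune and endothelial markers, and keratinocyte differentiation. Each list was tested against all other genes with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from each list's residuals. The p-values were adjusted over the 20 lists with Benjamini-Hochberg. Member genes were also counted with p-values adjusted over the list alone.

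The difference of mean log2 change between the arrest and apoptosis lists was tested by 100000 two-sided permutations of list membership, adjusted over 4 comparisons. The comparisons of both doses with 0 ng share their control arrays. The overlap and correlation of their changes were therefore set against simulated unchanged groups, against independent lists of the same sizes, and against values from controls split 2 and 2. Other splits of the arrays were refitted, all 35 for each pair of groups and 100 groupings for the interaction, the overlap and the correlation. The real grouping is counted among the 35 and among the 100, and the rest of the 100 were drawn.

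The alternatives were a replicate block, only the groups compared in the fit, quantile normalization, centring of each array on its median, removal of the dimmest 30% of genes (12891 left), the mean of a gene's clusters, all transcript clusters, trend and robust options in eBayes, array weights, each array left out in turn, and an estimated correlation for the lists. Quantile normalization together with an estimated correlation, or with each array left out in turn, and the 3 together, were added after the data were seen. The scripts were tested on simulated data made by redrawing residual arrays, and with independent noise, for 5 ng against 0 ng at 24 h over 18417 genes. With redrawn residual arrays on the values as deposited, the model called 64.2% of the changed genes at a log2 change of 1 and 100% at 2. After quantile normalization it called 85.1% and 98.5%. It made 0 false calls on both scales. At a log2 change of 0.5 it called 0% on the values as deposited and 49.3% after quantile normalization. With independent noise it called 2.99%, 64.2% and 100% at 0.5, 1 and 2 on both scales, with 5 false calls as deposited and 6 after quantile normalization. Each kind of noise was drawn 1 time, so these counts give no rate of false calls. Other splits of the real arrays of 12 h called up to 10997 genes on the values as deposited. Data were read with the data.table package in version 1.17.8, and figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.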

Results

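Gene expression was measured on 20 arrays in B5/589 mammary epithelial cells whose p53 transgene is switched on by doxycycline. The series asks whether p53 targets that arrest the cell cycle and those that promote apoptosis respond differently to a lower and a higher level of p53. Cells received 0, 3 or 5 ng of doxycycline and were collected after 24 h, and the induced cells also after 12 h, with 4 arrays in each of 5 groups. The means of the array medians were 5.07 at 0 ng, 5.15 and 4.96 at 12 h with 3 ng and 5 ng, and 4.85 and 4.80 at 24 h with 3 ng and 5 ng. The arrays of 24 h with doxycycline were thus the dimmest on average. Counts and directions are given on the deposited values and, beside them, after quantile normalization between arrays.

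**Figure D1:**
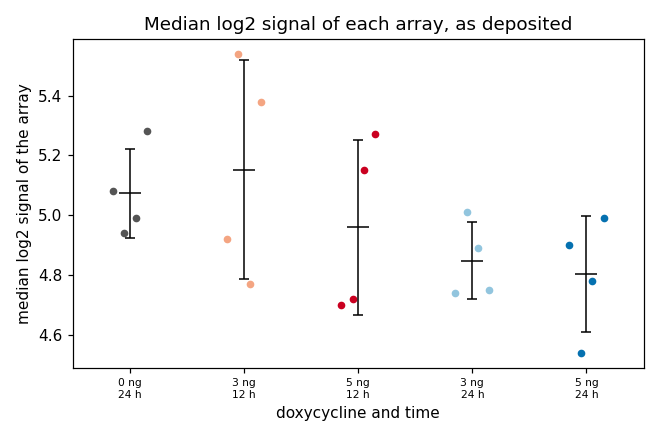
Median log2 signal of each of the 20 arrays (y axis) by group of doxycycline dose and time (x axis), each point 1 array. The medians run from 4.54 to 5.54, and the 4 arrays of 3 ng at 12 h spread most, with an SD of 0.37.

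The comparison of 3 ng with 0 ng at 24 h asks what the lower dose did. CRYAB, a small heat shock protein, rose by 4.91 ± 0.26 on the log2 scale (SE, n = 4 arrays in each group), which is 29.96-fold (limma with Benjamini-Hochberg, adjusted p = 9.8e-11). LCE1C and LCE1B, proteins of the cornified envelope of skin, rose 21.8-fold and 10.1-fold, AKR1B10, an aldo-keto reductase, 12.7-fold, and CLCA2, a membrane protein of epithelia, 9.35-fold. The p53 target TP53I3, a quinone oxidoreductase, rose by 2.93 ± 0.14 (7.63-fold). Transcripts of dividing cells fell. The log2 changes were -3.53 for the histone gene H2BC14, -2.87 for the mitotic kinase TTK, -3.04 for the kinesin KIF11, -2.81 for the proliferation marker MKI67, -2.75 ± 0.24 for CDK1, the kinase that drives entry into mitosis, and -2.09 ± 0.20 for its partner cyclin CCNB1.

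Of the 14 measured arrest targets, 2 rose and 1 fell, with the same count when p was adjusted over the list alone. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.72 ± 0.14 (1.64-fold, limma adjusted p = 0.00095), ZNF385A rose by 0.61, and E2F7, a repressor of E2F target genes, fell (-1.25). Of the 23 apoptosis targets, 7 rose and 3 fell (9 and 4 adjusted over the list alone). TP53I3, TP53INP1 (1.71), PIDD1 (1.12) and the caspase CASP10 (1.00) were among the risen. Of the 10 feedback regulators of p53, 2 rose, TRIM22 (0.69) among them, and 1 fell, WRAP53 (-0.75), against 2 and 2 adjusted over the list alone. Of the 23 repair and metabolism targets, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with GDF15, a secreted stress factor, at 1.14, SESN1 at 1.01 and SPATA18 at 0.96, and FANCC at -1.61. Among the other panel genes, FAS (0.40), SFN (0.25), MDM2 (0.18), GADD45A (0.09), BAX (-0.01), TNFRSF10B (-0.06) and BBC3 (-0.11) did not pass as deposited. After quantile normalization all of these but BBC3 (0.20) rose, FAS by 0.87, SFN by 0.63, GADD45A by 0.50, MDM2 by 0.48, BAX by 0.46 and TNFRSF10B by 0.38. PMAIP1, a pro-apoptotic BH3-only gene, fell by 0.51 (limma adjusted p = 0.030), a call that ended after quantile normalization (-0.03), after centring (-0.29), and without replicate 1 (-0.40) or 4 (-0.43) of 0 ng or replicate 2 (-0.50) or 4 (-0.42) of 3 ng. After quantile normalization 10 arrest targets rose and 1 fell, 16 apoptosis targets rose and 1 fell, and 18 repair and metabolism targets rose and 2 fell.

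All 29 G2 and M phase genes and all 31 S phase genes fell, before and after quantile normalization and with p adjusted over the list alone. So did 24 of 26 replication-dependent histones (24 adjusted over the list alone, 23 after quantile normalization). Among the S phase genes, EXO1 changed by -2.75, CLSPN by -2.70 and DTL by -2.54. Ribosome biogenesis genes fell in 18 of 19 (18 adjusted over the list alone, 16 with 1 rise after quantile normalization), with DKC1 at -1.11 and UTP20 at -1.08. Fewer members of the remaining lists passed, and several of these lists went the other way after quantile normalization. Cholesterol synthesis had 0 rises and 6 falls (7 adjusted over the list alone), EBP at -1.14 among them, but 3 rises and 1 fall after quantile normalization. Immediate early and MAPK feedback genes had 1 rise and 7 falls, also adjusted over the list alone, with ETV4 at -0.80, against 6 and 2 after quantile normalization. The same 2 sets of counts were 1 and 4 against 7 and 3 for NF-kB targets (CXCL8 -0.85), 1 and 3 against 7 and 2 for the unfolded protein list (TRIB3 -0.76), 0 and 3 against 4 and 1 for caspases and their inhibitors (CASP2 -0.87), and 0 and 2 against 5 and 1 for the BCL2 family (BCL2L11 -0.78). Adjusted over the list alone, the counts as deposited of these 4 lists did not move. None of 19 interferon-stimulated genes passed in limma, on either scale or adjusted over the list alone. Among the marker lists, 2 of 9 basal markers rose and 1 fell (MYLK 0.70, ACTA2 0.55), 2 of 14 luminal and 2 of 16 mesenchymal markers fell (CDH2 -0.97, SNAI2 -0.70), 1 of 13 immune and endothelial markers fell, and 2 of 17 keratinocyte genes rose and 1 fell. The ACTA2 call ended without replicate 2 of 0 ng (0.49) or replicate 2 of 3 ng (0.50). Adjusted over the list alone, the immune and keratinocyte lists had 0 calls, and the other 3 had the same counts. After quantile normalization the rises and falls were 6 and 0, 7 and 1, 2 and 2, 2 and 0, and 5 and 0 for these 5 lists.

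In all, 4504 of 18417 genes were called, of which 276 rose and 4228 fell, with 85 rises and 847 falls of at least 2-fold, and 5423 genes had groups that did not overlap (2.86% by chance). The median of all genes was -0.24 as deposited and 0.08 after quantile normalization, where 2834 genes rose and 2308 fell. The share of rises was then 55.1% against 6.13% (25.6%, or 814 of 3175 calls, with each array centred on its median), and 2552 genes were called in the same direction on both scales. Camera with the preset correlation called the arrest, apoptosis, and repair and metabolism targets up (adjusted p = 0.00047, 1.4e-08 and 9.2e-09), but adjusted p = 0.584, 0.435 and 0.435 with an estimated correlation. With the preset correlation it also called the G2 and M phase, S phase, histone and ribosome biogenesis lists down and the basal and keratinocyte lists up, with adjusted p = 0.059, 0.0603, 0.059, 0.502, 0.745 and 0.761 with an estimated correlation. On the quantile-normalized values camera with an estimated correlation called the arrest, apoptosis, and repair and metabolism targets up (adjusted p = 0.0123, 0.0066 and 0.00031) and the G2 and M phase, S phase, histone and ribosome biogenesis lists down (adjusted p = 0.0138, 0.0138, 0.0066 and 0.0303). The count of called genes was 2782 without replicate 4 of 0 ng and 2931 without replicate 4 of 3 ng.

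At 5 ng against 0 ng at 24 h, which asks what the higher dose did, CRYAB again had the largest rise called. It rose by 6.55 ± 0.26 (SE, n = 4 arrays in each group), or 93.9-fold, LCE1C 55.1-fold, LCE1B 25.1-fold, AKR1B10 23.3-fold, PALMD, a paralemmin family gene, 22.5-fold, and CLCA2 16.9-fold. TP53I3 rose by 3.53 ± 0.14. Among the falls, H2BC14 changed by -5.09 ± 0.24, PLK4, the kinase of centriole duplication, by -4.79, KIF11 by -4.76, XRCC2, a recombination gene, by -4.64, CDK1 by -3.88 (14.7-fold lower) and CCNB1 by -3.63 (12.4-fold lower).

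Among the 14 arrest targets 6 rose and 1 fell (7 and 2 adjusted over the list alone). CDKN1A rose by 1.44 ± 0.14 (2.70-fold), ZNF385A by 1.10, PLK3 by 0.92 and SFN, the 14-3-3 sigma gene, by 0.88, and E2F7 fell (-0.99). Among the 23 apoptosis targets 11 rose and 2 fell (12 and 2 adjusted over the list alone), with TP53INP1 at 2.66, IGFBP3 at 1.70, PIDD1 at 1.70 and FAS, a death receptor, at 1.04. Of 10 feedback regulators 3 rose and 1 fell, also adjusted over the list alone, with TRIM22 at 1.06. MDM2, the ligase that degrades p53, rose by 0.47, a call that ended without replicate 3 of 0 ng (0.35). Of 23 repair and metabolism targets 15 rose and 2 fell (15 and 3 adjusted over the list alone), with SESN1 at 1.80, GDF15 at 1.74 and TP53I11 at 1.52. GADD45A (0.42), TNFRSF10B (0.36), BAX (0.34), PMAIP1 (0.12) and BBC3 (-0.02) did not pass as deposited, and all 5 rose after quantile normalization, by 0.71, 0.68, 0.69, 0.49 and 0.30. After quantile normalization 10 arrest targets rose and 1 fell, 19 apoptosis targets rose and 2 fell, 6 feedback regulators rose and 1 fell, and 18 repair and metabolism targets rose and 2 fell.

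All 29 G2 and M phase genes and all 31 S phase genes fell again, on both scales and with p adjusted over the list alone, as did 23 of 26 histones (24 adjusted over the list alone, 23 after quantile normalization). CCNE2 changed by -4.11 and DTL by -4.28. Ribosome biogenesis genes fell in 18 of 19, also adjusted over the list alone (17 and 1 rise after quantile normalization). Of 9 basal markers 5 rose and 1 fell, also adjusted over the list alone (7 and 0 after quantile normalization), with MYLK at 1.18, ACTA2 at 0.85, KRT5 at 0.66 and KRT14 at 0.56. Of 14 luminal markers 3 rose and 1 fell, also adjusted over the list alone (9 and 1 after quantile normalization), with KRT8 at 0.53 and EPCAM at -0.85. Keratinocyte genes rose in 3 and fell in 1 of 17 (2 and 0 adjusted over the list alone, 9 and 0 after quantile normalization), with FLG, the filaggrin gene, at 1.62 and LCE3D at 1.26. The unfolded protein list had 3 rises and 3 falls of 15, also adjusted over the list alone (CHAC1 0.95, TRIB3 -0.92), the BCL2 family 3 rises and 0 falls of 14, also adjusted over the list alone (BAK1 0.98), and caspases and their inhibitors 2 and 2 of 12 (2 and 4 adjusted over the list alone, CFLAR 0.83, CASP2 -1.07). Immediate early and MAPK feedback genes had 3 rises and 8 falls of 20 (4 and 8 adjusted over the list alone, DUSP1 0.94, DUSP6 -0.99), NF-kB targets 3 and 5 of 18, also adjusted over the list alone (MMP3 -1.52, CXCL8 -1.02), and cholesterol synthesis 0 and 6 of 16 (0 and 7 adjusted over the list alone, EBP -1.28, INSIG1 -0.79). After quantile normalization these 6 lists had 10 and 3, 6 and 0, 6 and 2, 6 and 5, 9 and 4, and 2 and 5. Mesenchymal markers fell in 4 of 16, also adjusted over the list alone (CDH2 -1.16), and immune and endothelial markers in 2 of 13 (1 adjusted over the list alone, CD14 -1.43), with 2 rises and 2 falls, and 3 and 1, after quantile normalization. Interferon-stimulated genes had 0 calls in limma, also adjusted over the list alone, and 3 rises after quantile normalization.

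**Figure D2:**
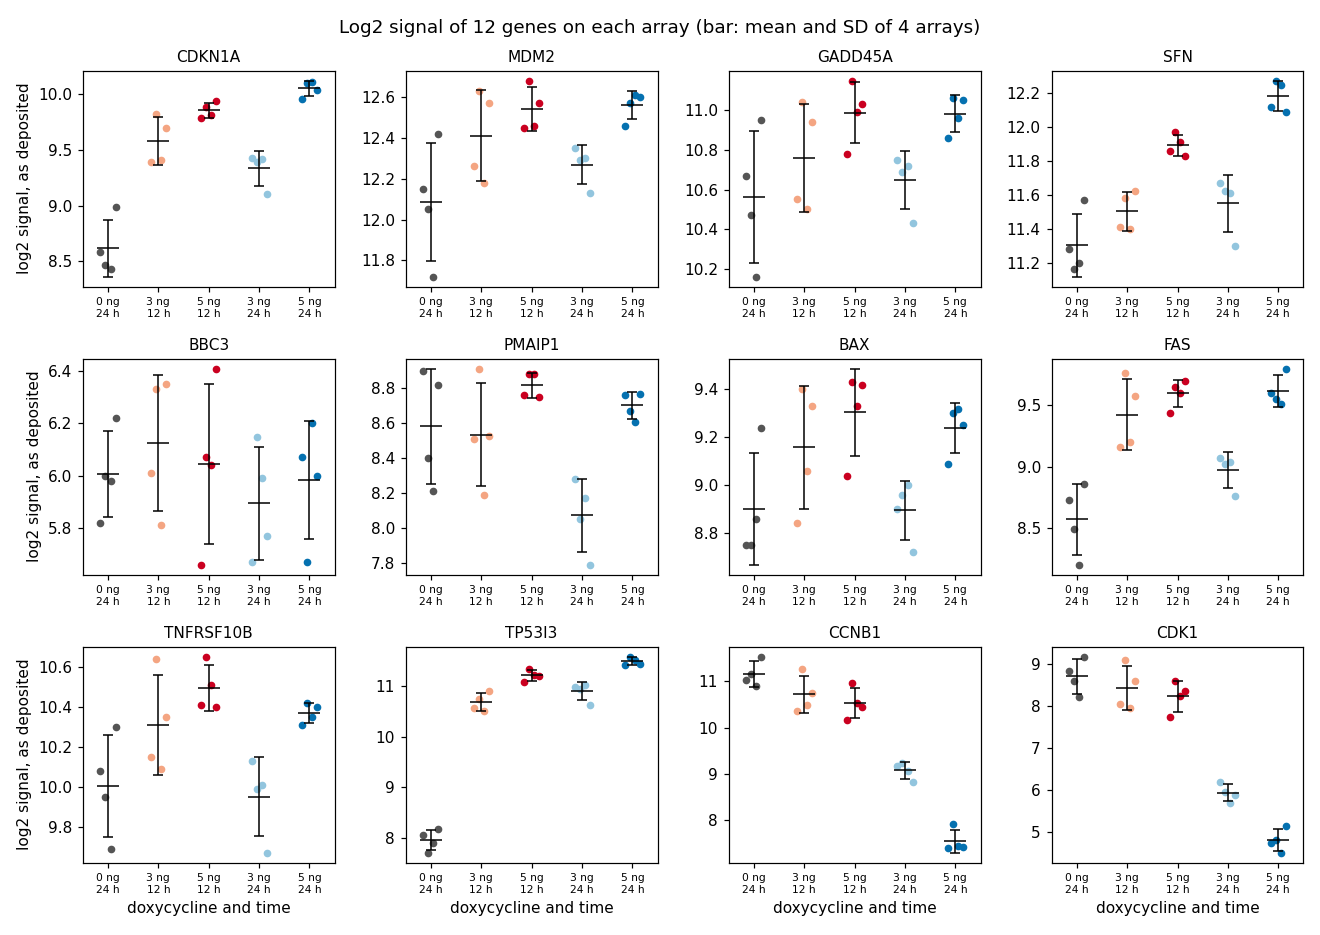
Log2 signal (y axis) of the 12 measured panel genes in the 5 groups (x axis), each point 1 array, with the mean and SD of 4 arrays. TP53I3 was higher at 24 h by 2.93 at 3 ng and 3.53 at 5 ng than at 0 ng, and the differences of CCNB1 were -2.09 and -3.63.

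At 5 ng, 5166 genes were called against 0 ng, 833 up and 4333 down, with 308 rises and 1213 falls of at least 2-fold, and 5878 had groups that did not overlap (2.86% by chance). The median of all genes was -0.24 as deposited and 0.07 after quantile normalization, where 3786 rose and 3172 fell (54.4% rises against 16.1%, and 44.3%, or 2172 of 4902, after centring) and 3977 genes kept their call and direction. Camera with the preset correlation called 12 lists, among them the arrest, apoptosis, feedback, and repair and metabolism targets, with adjusted p = 0.322, 0.142, 0.527 and 0.194 with an estimated correlation. The G2 and M phase, S phase and histone lists each had adjusted p = 0.0674 with an estimated correlation, and the ribosome, basal, luminal, unfolded protein and keratinocyte lists 0.467, 0.322, 0.606, 0.674 and 0.527. With the estimated correlation after quantile normalization, camera called the arrest, apoptosis, and repair and metabolism targets up (adjusted p = 0.0153, 0.0058 and 0.00047) and the G2 and M phase, S phase, histone and ribosome biogenesis lists down (adjusted p = 0.0222, 0.0222, 0.0149 and 0.0272). Between the doses, 270 of the 276 genes that rose at 3 ng also rose at 5 ng, and 3643 of the 4228 that fell also fell, with 0 in opposite directions. Independent lists of these sizes would share 12.5 and 995, and unchanged groups simulated against the same controls shared a median of 0. The correlation of the changes across genes, which are not independent replicates, was 0.912 (0.497 in the simulation) and the covariance 0.257 (0.0157 in the simulation, a difference of 0.241). With the controls split 2 and 2, 155 to 247 genes rose and 1241 to 2064 fell at both doses, with correlations of 0.762 to 0.834 and covariances of 0.236 to 0.244. Without replicate 4 of 0 ng the overlap of 3913 genes was 2571.

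The comparison of 5 ng with 3 ng at 24 h measures the dose difference itself. PLA2G10, a secreted phospholipase, was 5.35-fold higher at 5 ng (log2 2.42 ± 0.45, SE, n = 4 arrays in each group), PALMD 4.63-fold (2.21 ± 0.22), and CRYAB 3.13-fold (1.65 ± 0.26). ID2, an inhibitor of bHLH factors, rose by 1.71 and the chemokine CCL3 by 1.61. Lower at 5 ng were XRCC2 (-1.91), NUF2, a kinetochore gene (-1.83), TTK (-1.76), CCNE2 (-1.72) and CCNB1 (-1.54 ± 0.20).

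Of the 14 arrest targets 3 rose and 0 fell (6 and 0 adjusted over the list alone), namely CDKN1A by 0.72 ± 0.14 (1.64-fold, limma adjusted p = 0.0055), PLK3 by 0.64 and SFN by 0.63. Of the 23 apoptosis targets 9 rose and 0 fell (14 and 0 adjusted over the list alone), with APAF1, the apoptosome scaffold, at 1.21 ± 0.16 (2.31-fold), CASP6 at 1.08 and TP53INP1 at 0.95. The rises of FAS (0.64) and PMAIP1 (0.63) were lost without any 1 of the 8 arrays, with log2 values from 0.57 to 0.68 and from 0.54 to 0.70. That of TP53I3 (0.60) was lost without replicate 4 of 3 ng (0.51) or replicate 2 (0.57) or 3 (0.59) of 5 ng, and the fall of CDK1 (-1.13) without replicate 3 of 5 ng (-1.03). After quantile normalization of all arrays the calls of FAS, PMAIP1, TP53I3 and CDK1 held. Of 10 feedback regulators 1 rose, also adjusted over the list alone, and of 23 repair and metabolism targets 6 rose (15 adjusted over the list alone), with TP53I11 at 0.84. MDM2 (0.29), GADD45A (0.34), BBC3 (0.09), BAX (0.34) and TNFRSF10B (0.42) did not pass as deposited, and of these GADD45A (0.21) and TNFRSF10B (0.30) did after quantile normalization. After quantile normalization 7 arrest targets rose, 15 apoptosis targets rose and 1 fell, and 14 repair and metabolism targets rose.

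G2 and M phase genes fell in 26 of 29 (28, with 1 rise, adjusted over the list alone and after quantile normalization), S phase genes in 21 of 31 (24 adjusted over the list alone, 27 after quantile normalization), and histones in 4 of 26 (15 adjusted over the list alone, 11 after quantile normalization). BCL2L11, a BH3-only gene, rose by 0.82 and BAK1 by 0.70, the 2 rises of the BCL2 family, also adjusted over the list alone. CHAC1 rose by 0.90 as the single call of the unfolded protein list, and EGR1 by 0.83 as 1 of 3 rises of the immediate early list, both counts the same adjusted over the list alone. The keratinocyte list had 2 rises, also adjusted over the list alone, FLG at 1.10 and LCE3D at 0.77. The CHAC1 call ended without replicate 4 of 3 ng (0.82) or replicate 1 of 5 ng (0.81), and the LCE3D call with only the 8 arrays compared in the fit (limma adjusted p = 0.0511) and without replicate 4 of 3 ng (0.59) or replicate 3 of 5 ng (0.71). The basal list had 0 calls as deposited, 4 rises adjusted over the list alone and 2 after quantile normalization. The other 8 lists had 0 calls in limma over all genes, and adjusted over the list alone 2 caspases and inhibitors rose, 2 NF-kB targets rose and 1 fell.

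There were 468 genes called between the doses at 24 h, 329 up and 139 down, with 71 and 98 of at least 2-fold, and 2065 had groups that did not overlap (2.86% by chance). After quantile normalization 1097 rose and 814 fell (57.4% rises against 70.3%), and 466 genes kept their call. The arrest, apoptosis, and repair and metabolism lists were called up by camera with the preset correlation, with adjusted p = 0.283, 0.161 and 0.283 with an estimated correlation. The G2 and M phase list kept its call (adjusted p = 0.0436 with an estimated correlation), while the S phase and histone lists did not (adjusted p = 0.103 and 0.201). The same held for the feedback, basal, BCL2 family, unfolded protein, immediate early, luminal and keratinocyte lists, with adjusted p = 0.421, 0.283, 0.619, 0.619, 0.725, 0.624 and 0.619 with an estimated correlation. Camera with the estimated correlation after quantile normalization called the arrest, apoptosis, and repair and metabolism targets up (adjusted p = 0.0131, 0.0022 and 0.00043) and the G2 and M phase and S phase lists down (adjusted p = 0.0238 and 0.0451), the S phase call ending without replicate 1 or 4 of either dose (up to 0.0665). The 468 calls were 276 without replicate 4 of 3 ng, 302 without replicate 3 of 5 ng and 304 without replicate 4 of 5 ng.

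The means of the arrest and apoptosis lists were then set against each other. At 24 h the 14 arrest targets were higher at 5 ng than at 3 ng by 0.28 ± 0.31 (SD over genes) and the 23 apoptosis targets by 0.47 ± 0.35, a difference of -0.18 (95% interval -0.40 to 0.02, permutation p = 0.115, adjusted p = 0.235). Of the arrest targets 10 of 14 lay above 0, and of the apoptosis targets 21 of 23. At 12 h the values were 0.07 ± 0.25 and 0.19 ± 0.25 (difference -0.12, interval -0.29 to 0.04, permutation p = 0.176, adjusted p = 0.235), with 9 of 14 and 18 of 23 above 0. Against 0 ng at 24 h, arrest targets changed on average by 0.04 ± 0.49 at 3 ng and 0.32 ± 0.69 at 5 ng, and apoptosis targets by 0.31 ± 0.81 and 0.78 ± 1.03. These differences were -0.28 (interval -0.72 to 0.10, permutation p = 0.273, adjusted p = 0.273) and -0.46 (interval -1.02 to 0.06, permutation p = 0.149, adjusted p = 0.235). None of the 4 differences passed, and the intervals reach to -1.02. As deposited, the differences of medians against 0 ng were 0.01 at both doses, with the other sign. After quantile normalization arrest targets changed on average by 0.43 at 3 ng and 0.64 at 5 ng against 0 ng at 24 h. Apoptosis targets changed by 0.72 and 1.11. Between the doses the arrest and apoptosis means were 0.21 and 0.39 at 24 h, and 0.13 and 0.24 at 12 h. On that scale the 4 differences had permutation p from 0.095 to 0.241 before adjustment. Genes of a list are not independent replicates.

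The same doses were also compared after 12 h. Of the panel genes, TP53I3 was higher at 5 ng by 0.53 ± 0.14 (SE, n = 4 arrays in each group), SFN by 0.39, CDKN1A and PMAIP1 by 0.28, GADD45A by 0.23, TNFRSF10B by 0.18, FAS by 0.17, BAX by 0.15 and MDM2 by 0.13, BBC3 differed by -0.08, CCNB1 by -0.19 and CDK1 by -0.20, and none of these passed in limma. After quantile normalization TP53I3 (0.50, limma adjusted p = 0.0015), SFN (0.37, adjusted p = 0.011) and CDKN1A (0.29, adjusted p = 0.022) did. PALMD (1.34), LCE1F (1.01), ARRB1, an arrestin, (0.90) and FRMD8 (0.80) rose, the 4 calls in limma against 1082 genes at an unadjusted p under 0.05.

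Over all genes no list had a member called at 12 h. Adjusted over the list alone, 5 apoptosis targets rose, 18 S phase genes fell and 13 histones fell. After quantile normalization 3 arrest, 5 apoptosis and 5 repair and metabolism targets rose, and 12 S phase genes and 9 histones fell. Camera with the preset correlation called 11 lists, these 5 among them. With an estimated correlation it called 0 lists, with adjusted p = 0.467, 0.321 and 0.364 for the p53 targets and 0.321 each for the S phase genes and histones. Quantile-normalized values with the estimated correlation gave calls for the apoptosis targets and the repair and metabolism targets, both up (adjusted p = 0.0108 and 0.0011). The arrest targets were also called up and the histones down (adjusted p = 0.0411 each), but neither without any 1 of replicates 2, 3 and 4 of 3 ng and 1, 3 and 4 of 5 ng (up to 0.0843). The median of all genes was -0.12, and 220 genes (1.19%) had groups that did not overlap, fewer than the 2.86% that chance gives. After quantile normalization 428 genes rose and 78 fell (84.6% rises against 100%), and these 506 calls were 245 without replicate 2 of 3 ng and 236, 261 and 301 without replicates 1, 3 and 4 of 5 ng. The 4 calls became 0 with only the 8 arrays compared in the fit, 0 without replicate 1 or 3 of 3 ng or replicate 1 or 4 of 5 ng, 1 without replicate 2 or 3 of 5 ng, and 11 without replicate 4 of 3 ng.

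**Figure D3:**
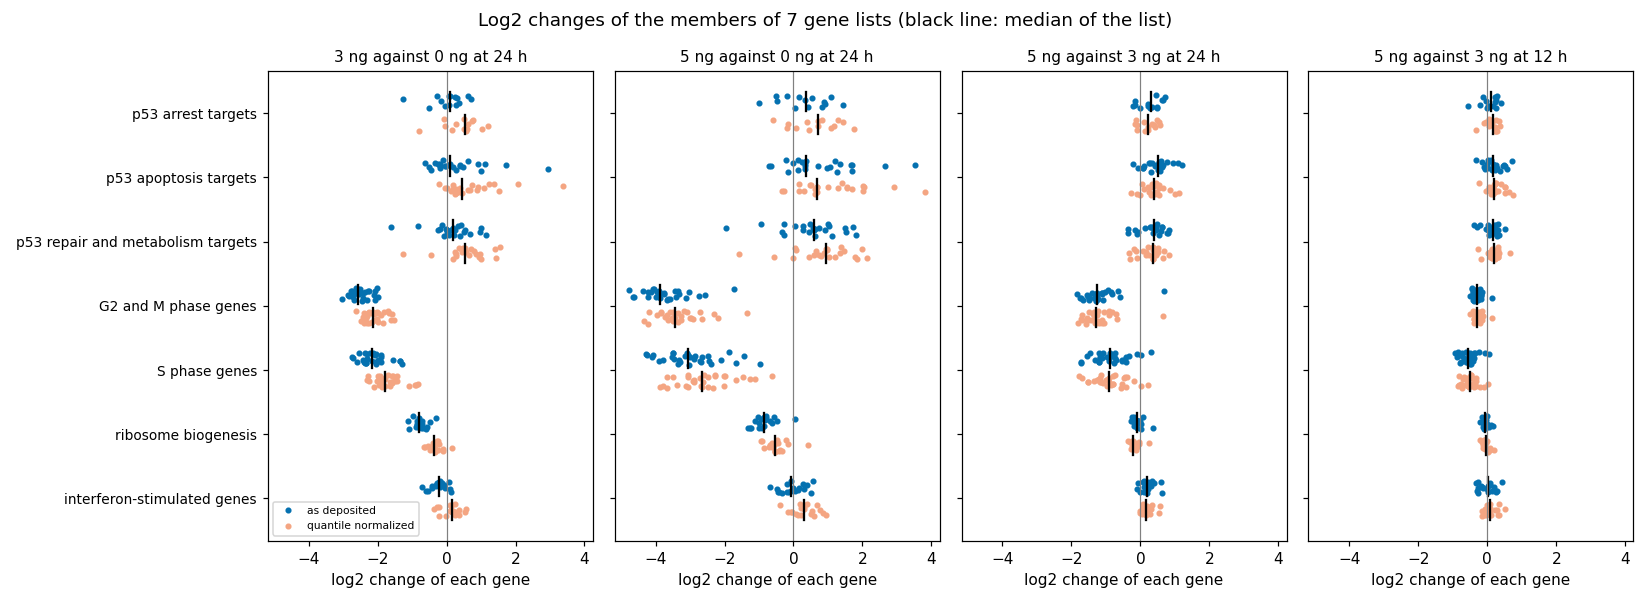
Log2 change (x axis) of each measured member of 7 gene lists (y axis) in 4 comparisons, blue as deposited and orange after quantile normalization, with a black line at the list median. The G2 and M phase medians were -2.58 and -3.88 at 3 ng and 5 ng against 0 ng at 24 h, -1.26 between the doses at 24 h and -0.29 between them at 12 h.

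The dose differences at the 2 times were compared across all 18417 genes, which are not independent replicates. They correlated with r = 0.524 and rho = 0.517 (0.498 and 0.445 after quantile normalization), from 0.426 without replicate 2 of 5 ng at 24 h to 0.563 without replicate 1 of 3 ng at 24 h. Over all transcript clusters r was 0.222, and with array weights 0.254. Of the 833 genes that rose at 5 ng at 24 h, 94.1% were higher at 5 ng than at 3 ng after 12 h, against 24.7% of all genes (84.2% against 50.2% after quantile normalization). Of the genes that fell at 5 ng at 24 h, 7.55% were higher (17.2% after quantile normalization).

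Induced cells at 12 h were compared with the uninduced cells of 24 h, a comparison in which dose and time differ together. At 3 ng, CRYAB was 13.9-fold higher (log2 3.80), LCE1C rose by 3.78 and AKR1B10 by 3.63 (n = 4 arrays in each group). TP53I3 rose 6.59-fold, TP53INP1 by 1.75, APAF1 by 1.57, SESN1 by 1.70 and CDKN1A 1.95-fold (0.96). FAS was 0.86 higher, a call lost with only the 8 arrays compared in the fit (limma adjusted p = 0.064). At 5 ng, CRYAB rose 36.6-fold, LCE1C 29.0-fold, TP53I3 9.50-fold, APAF1 by 2.06, CDKN1A 2.36-fold (1.24), FAS by 1.03 and SFN by 0.59.

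Genes of DNA replication fell at 12 h. At 3 ng, CCNE2 changed by -1.55 and UNG, a uracil glycosylase, by -1.21, while CCNB1 (-0.44) and CDK1 (-0.28) did not pass. At 5 ng, CCNE2 changed by -2.48 (5.59-fold lower), POLE2, a DNA polymerase subunit, by -2.08 and DTL by -1.95, while CDK1 (-0.47) did not pass. Of the 31 S phase genes 20 fell at 3 ng and 28 at 5 ng (28 and 29 adjusted over the list alone, 27 and 28 after quantile normalization), of the 26 histones 9 and 22 (20 and 22 adjusted over the list alone, 18 and 22 after quantile normalization), and of the 29 G2 and M phase genes 1 and 24 (13 and 27 adjusted over the list alone, 2 and 23 after quantile normalization). Arrest targets rose in 2 and 6 of 14 (3 and 8 adjusted over the list alone), apoptosis targets in 9 and 12 of 23 (9 and 14), and repair and metabolism targets in 9 and 13 of 23 (12 and 14), with 10 and 10, 16 and 19, and 16 and 17 after quantile normalization. Cholesterol synthesis genes fell in 2 and 8 of 16 (10 and 10 adjusted over the list alone, 7 and 9 after quantile normalization), with INSIG1 at -0.90 and -1.22. At 3 ng MDM2 (0.33), TNFRSF10B (0.30), BAX (0.26), GADD45A (0.20), SFN (0.20), BBC3 (0.12) and PMAIP1 (-0.05, 0.18 after quantile normalization) did not pass as deposited, and the first 5 did after quantile normalization (0.53, 0.56, 0.50, 0.44 and 0.42). At 5 ng GADD45A (0.42), BAX (0.41), PMAIP1 (0.24) and BBC3 (0.04) did not, and all but BBC3 did after quantile normalization (0.65, 0.66 and 0.50). TNFRSF10B (0.49), MDM2 (0.46) and CCNB1 (-0.63) passed at 5 ng but lost their calls with only the 8 arrays compared. TNFRSF10B also lost it without replicate 1, 2 or 3 of either group (0.38 to 0.52), MDM2 without any array but replicate 4 of 0 ng (0.33 to 0.49), and CCNB1 after centring (-0.52), without replicate 1, 3 or 4 of 5 ng (-0.51, -0.63, -0.61) and without replicate 1, 2 or 4 of 0 ng (-0.68, -0.63, -0.51).

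At 3 ng 519 genes were called, 290 up and 229 down, and 775 had groups that did not overlap (2.86% by chance). At 5 ng 2750 were called, 633 up and 2117 down, and 3719 did not overlap, with a median of all genes of -0.18. After quantile normalization 1218 rose and 1579 fell at 3 ng (43.5% rises against 55.9%), and 2110 rose and 2632 fell at 5 ng (44.5% against 23.0%, median -0.02). With centred arrays 557 of 3620 calls rose at 3 ng and 1082 of 3046 at 5 ng. Camera with an estimated correlation called 0 lists at either dose, with adjusted p = 0.357 for apoptosis targets, S phase genes and histones at 3 ng and 0.152 for each at 5 ng, while with the preset correlation it called 10 and 12. With quantile-normalized values the estimated correlation called the arrest, apoptosis, feedback, and repair and metabolism targets up at 3 ng (adjusted p = 0.0002, 0.00015, 0.018 and 1.8e-05) and 5 ng (adjusted p = 0.00069, 0.00035, 0.0319 and 3.7e-05). It called the keratinocyte list up at both doses (adjusted p = 0.023 and 0.0317) and at 5 ng the histones down (adjusted p = 0.0319). The basal list was called up as well (adjusted p = 0.0487 and 0.0344), a call that ended at 3 ng without replicate 1 or 3 of 3 ng or replicate 2, 3 or 4 of 0 ng (up to 0.0797) and at 5 ng without replicate 1 of 5 ng (0.0516). At 3 ng the count was 313, 2782 and 257 without replicates 1, 2 and 4 of 3 ng and 301, 294 and 319 without replicates 1, 2 and 4 of 0 ng, and at 5 ng 1510 without replicate 1 of 5 ng and 1819 and 1540 without replicates 1 and 4 of 0 ng.

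From 12 h to 24 h at the same dose, the largest changes called were falls, among them those of mitotic genes and, at 3 ng, of the histone gene H2BC14. The labels list no uninduced cells of 12 h, so time in culture and longer induction cannot be told apart in this comparison. At 3 ng, KIF14, a kinesin, changed by -2.52, H2BC14 by -2.51, CDK1 by -2.48 ± 0.24 (5.58-fold lower, n = 4 arrays in each group), ASPM, a spindle pole gene, by -2.41 and CCNB1 by -1.65 (3.14-fold lower). At 5 ng, KIF14 fell 14.6-fold, ASPM changed by -3.72, TTK by -3.70, CDK1 by -3.41 (10.6-fold lower) and CCNB1 fell 7.97-fold. All 29 G2 and M phase genes fell at both doses, on both scales and adjusted over the list alone. S phase genes fell in 28 and 29 of 31 (31 and 31 adjusted over the list alone, 30 and 31 after quantile normalization) and histones in 23 and 20 of 26 (24 and 23 adjusted over the list alone, 24 and 22 after quantile normalization).

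CRYAB rose further, by 1.11 at 3 ng and 1.36 at 5 ng, CLCA2 by 0.76 at 3 ng, and LOX, a collagen cross-linking enzyme, by 1.15 and LCE1C by 0.93 at 5 ng. The LCE1C call ended without any array of these groups but replicate 1 of 12 h (0.88 to 0.95). Among the p53 targets APAF1 (-1.10) and E2F7 (-1.11) fell at 3 ng. CDKN1A (-0.25 and 0.20), TP53I3 (0.21 and 0.28), FAS (-0.45 and 0.02) and PMAIP1 (-0.46 at 3 ng) did not pass as deposited. After quantile normalization TP53I3 rose at both doses (0.38 and 0.33), CDKN1A rose at 5 ng (0.25) and FAS fell at 3 ng (-0.24). Of the 14 arrest targets 1 fell at each dose (2 and 1 adjusted over the list alone), of the 23 apoptosis targets 1 and 0 (8 and 0 adjusted over the list alone), and of the 23 repair and metabolism targets 4 and 0 (5 and 0 adjusted over the list alone). After quantile normalization the rises and falls at 5 ng were 5 and 2, 5 and 2, and 7 and 1. Ribosome biogenesis genes fell in 1 and 2 of 19 (3 and 9 adjusted over the list alone, 9 and 14 after quantile normalization).

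At 3 ng 816 genes were called, 13 up and 803 down, and at 5 ng 731, 78 up and 653 down, while 1569 and 2101 had groups that did not overlap (2.86% by chance). The medians of all genes were -0.23 and -0.08. After quantile normalization they were 0.08 and 0.07, 1827 genes rose and 1116 fell at 3 ng (62.1% rises against 1.59%), and 1986 rose and 1400 fell at 5 ng (58.7% against 10.7%). With centred arrays 392 of 883 calls rose at 3 ng and 565 of 1246 at 5 ng. With an estimated correlation, the G2 and M phase, S phase and histone lists kept their calls (adjusted p = 0.0084, 0.0355 and 0.0084 at 3 ng, 0.0027, 0.014 and 0.0135 at 5 ng). With the G2 and M phase list between the doses at 24 h and in the interaction, these were all the calls of the 20 lists on the deposited values that held with an estimated correlation. The same 3 lists were called down at each dose after quantile normalization with an estimated correlation, and the ribosome biogenesis list also at 5 ng (adjusted p = 0.026). The 816 calls were 1328, 484, 1395 and 523 without replicates 1 to 4 of 3 ng at 12 h in turn, and 501 without replicate 4 of 3 ng at 24 h.

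The interaction asks whether the dose difference itself differed between 24 h and 12 h. The G2 and M phase list had a median interaction of -0.98 (-1.03 after quantile normalization), where a value below 0 is a dose difference that lies lower at 24 h than at 12 h. Of 100 groupings of the doses within each time, the real one included, 11 gave a median as far from 0, and 5 did after quantile normalization. CCNB1 had -1.34 (limma adjusted p = 0.86) as deposited and -1.38 (adjusted p = 0.0030) after quantile normalization, and CDK1 -0.93, CDKN1A 0.44, FAS 0.47 and PMAIP1 0.35 as deposited, none of which passed. The limma model called 0 genes, with 391 at an unadjusted p under 0.05, and 13 after quantile normalization, 1 up and 12 down. These 13 were 26 without replicate 2 of 3 ng at 12 h, 45 without replicate 2 of 5 ng at 24 h, 9 without replicate 3 of 3 ng at 24 h, and 2 to 8 without each of the other 13 arrays. The median interaction of all genes was 0.12 as deposited and -0.01 after quantile normalization. Adjusted over the list alone, 22 of the 29 G2 and M phase genes were called below 0, and 0 of any p53 target list. Camera called the G2 and M phase list with both correlations (adjusted p = 0.0076 with an estimated correlation). The apoptosis list, with a median of 0.28 (0.14 after quantile normalization), was called with the preset correlation (adjusted p = 6.8e-05) but had adjusted p = 0.952 with an estimated correlation. On the quantile-normalized values the estimated correlation called the G2 and M phase list down (adjusted p = 0.029), and the repair and metabolism targets (adjusted p = 0.029) and the apoptosis targets (adjusted p = 0.038) up. With 1 array left out these calls were kept in 12, 11 and 4 of 16 runs. The G2 and M phase call ended without replicate 3 or 4 of 3 ng at 12 h, replicate 2 of 3 ng or replicate 3 of 5 ng at 24 h (up to 0.0605), the repair and metabolism call without these 4 arrays or replicate 4 of 5 ng at 12 h (up to 0.0614). The apoptosis call was kept only without replicate 2 of 3 ng or replicate 3 of 5 ng at 12 h, or replicate 3 of 3 ng or replicate 2 of 5 ng at 24 h (0.0095 to 0.0878 over all runs).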

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

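The tests of a single offset per array, of array brightness for the G2 and M phase and apoptosis lists, and the redraw of the G2 and M phase list after quantile normalization were chosen only after the result was seen. The verdict rules of the test of brightness slopes, 2 times, and of the test of a single offset were also changed after their results were seen.

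Against uninduced cells at 24 h, 6.13% of the called genes rose at 3 ng and 16.1% at 5 ng. A single offset per array is argued against as the whole cause at 3 ng, where 25.6% of calls rose with centred arrays (20.99 to 27.66% with 1 array left out), and stays open at 5 ng, where 44.3% did (37.6 to 48.5%), since centring itself draws the shares of rises and falls together. Brightness that shifts genes unequally was tested by correlating, across genes, the slope on array brightness within other treated groups with the change, which gave r = 0.0368 (-0.0278 to 0.153 with 1 array left out) at 3 ng and -0.0916 (-0.147 to 0.0207) at 5 ng. Both r met the bound set beforehand against brightness, above -0.2, but the verdict was left open after the result was seen, because slopes this noisy would give an r of only -0.09 and -0.04 if brightness were the cause, so the bound could not have been missed. An effect of p53 on total transcript levels, a biological explanation that the doses name, was not tested and stays open too.

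The G2 and M phase list had a median interaction of -0.98, with 0 members called in limma over all genes as deposited and 6 after quantile normalization. Array brightness as the whole cause is argued against by the median of -1.03 after quantile normalization, with 28 of 29 members below 0. A single array is argued against by the leave-one-out medians, from -1.16 to -0.83. Chance could not be excluded, since 11 of 100 groupings of the doses within each time, the real one included, gave a median as far from 0 (highest other 1.46), and 5 of 100 after quantile normalization (highest other 1.36). A later or longer action of the higher dose is a biological candidate explanation that was not tested separately.

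The p53 apoptosis targets had a median interaction of 0.28, or 0.14 after quantile normalization, with 18 of 23 members above 0. Whether brightness accounts for it stays open. After quantile normalization and with an estimated correlation camera gave adjusted p = 0.038, but with 1 array left out it ran from 0.0095 to 0.088 and was under 0.05 in 4 of 16 runs. Chance could not be excluded, since 36 of 100 groupings, the real one included, gave a median as far from 0 as 0.141 (highest other 0.393). A dose threshold of these genes, the biological explanation in the design, was not shown or excluded.

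Other splits of the arrays were refitted for each count of called genes. Of the 35 splits of 8 arrays into 4 and 4, only the real one called as many for 3 ng against 0 ng (4504, highest other 1), 5 ng against 0 ng (5166, highest other 0) and 5 ng against 3 ng at 24 h (468, highest other 0), for 5 ng at 12 h against 0 ng (2750, highest other 1) and for 24 h against 12 h at 3 ng (816, highest other 0). This argues against chance there, but 1 of 35 is the smallest share possible, and the 8 comparisons were not corrected for one another. Chance was not excluded for 5 ng against 3 ng at 12 h (3 of 35 splits, 4 genes against 10997), 3 ng at 12 h against 0 ng (3 of 35, 519 against 7713) and 24 h against 12 h at 5 ng (2 of 35, 731 against 1483). Those large counts point to a structure of the samples, and these 3 largest splits follow array brightness, with medians of 4.70 to 4.92 against 5.15 to 5.54, of 4.77 to 4.99 against 5.08 to 5.54, and of 4.54 to 4.78 against 4.90 to 5.27. After quantile normalization each of these 3 splits called 0 genes. The array medians overlapped in the other splits larger than the real one, with 1459 genes for 5 ng against 3 ng at 12 h (4.92 to 5.54 against 4.70 to 5.15, 0 genes after quantile normalization) and 4980 for 3 ng at 12 h against 0 ng (4.77 to 5.38 against 4.94 to 5.54, 126 genes after quantile normalization). What sets those 2 splits apart was not tested. On that scale only the real split was as large for each of the 8 comparisons of 2 groups, which argues against chance with the same limit (highest others 1 for 3 ng and 2 for 5 ng against 0 ng at 24 h, 1 for each dose difference, 126 and 1 for 3 ng and 5 ng at 12 h, 1 and 3 for the times).

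For the interaction, all 100 groupings, the real one included, called at least the 0 genes of the deposited values (highest other 5866). After quantile normalization 3 of 100 called as many as 13 (highest other 193). On that scale the share lay under the 5 in 100 set beforehand as counting against chance. Redraws other than the real grouping called as many or more, so chance is not excluded. Nor was the count of 13 stable, with 45 and 26 without replicate 2 of 5 ng at 24 h and replicate 2 of 3 ng at 12 h, 9 without replicate 3 of 3 ng at 24 h, and 2 to 8 without each of the other 13 arrays. The counts of lists called with the preset correlation on the deposited values were also reached by other groupings in every comparison. Splits that mix the 2 groups unequally keep part of the real difference, so these shares cannot decide about chance. Lists called with an estimated correlation were not put to such splits. The shares that follow count the real grouping. As many lists were called by 11, 10, 7, 7, 12, 8, 10 and 12 of 35 splits, in the order 3 ng and 5 ng against 0 ng at 24 h (9 and 12 lists, highest others 14 and 15), dose difference at 24 h and 12 h (13 and 11, highest others 15 and 12), 3 ng and 5 ng at 12 h against 0 ng (10 and 12, highest others 12 and 14), and 24 h against 12 h at 3 ng and 5 ng (8 and 8, highest others 11 and 14), and by 52 of 100 redraws for the interaction (8 lists, highest other 15). The overlap of calls between the doses was reached only by the real grouping (1 of 100 groupings, 3913 genes, highest other 3758), which argues against chance. Both doses share the 0 ng arrays, so this cannot tell agreement between the doses from a difference of those controls. The correlation of the dose differences was reached by 2 of 100 (r = 0.524, highest other 0.545). This share lay under the 5 in 100 set beforehand as counting against chance. A redraw gave a larger r, so chance is argued against but not excluded.

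In 8 of 165 sets of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20. Replicate 4 of 3 ng at 24 h was low for CDKN1A (9.10 against 9.39 to 9.43), SFN (11.30 against 11.61 to 11.67), FAS (8.76 against 9.02 to 9.07) and the mean of the repair and metabolism targets (7.68 against 7.89 to 7.94). After quantile normalization this array lay nearer the others for these 3 genes. The values were 9.47 against 9.50 to 9.62, 11.65 against 11.71 to 11.79, and 9.12 against 9.13 to 9.24. Replicate 2 of 5 ng at 24 h was high for CCNB1 (7.90 against 7.39 to 7.43), and replicate 4 of that group for the mean of the p53 feedback regulators (8.42 against 8.15 to 8.17). Replicate 1 of 5 ng at 12 h was low for the unfolded protein list (8.65 against 8.85 to 8.89), and replicate 1 of 5 ng at 24 h for the NF-kB targets (8.62 against 8.65 to 8.65).

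The interaction passed for 13 genes after quantile normalization, some of them named here after their values were seen, and for 2 to 45 genes with 1 array left out, the count without each array being given with the interaction in the results. DEPDC1 had -1.53, CCNB1 -1.38, SHCBP1 -1.27, CCNA2 -1.21, AURKA -1.20, HMMR -1.13, TPX2 -1.10, TOP2A -1.09, PRC1 -1.07, ANLN -1.03, RRM2 -0.86 and CKS2 -0.81, and APAF1 had 0.60. Transcript clusters outside the named genes also changed at 5 ng against 0 ng at 24 h, with 85 rises and 1107 falls among the 12083 not listed in the annotation, and 49 rises and 297 falls among the 1754 with several symbols.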

How the results depend on the processing

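Quantile normalization together with an estimated correlation or with 1 array left out, and all 3 together, were chosen only after the data were seen, and the other alternatives given here were planned. Those that refit single genes, other than over all transcript clusters and the 3 added ones, were run on 361 values of named genes (356 with dim genes left out), and none of the 272 called values changed direction in them. The calls lost were 17 with only the groups compared, 6 with centring, 3 with quantile normalization, 1 with the mean of a gene's clusters and 0 with array weights, the trend and robust options or dim genes left out, and 147 of 3080 values lost their call when 1 array was left out. Calls gained numbered 42 with array weights, 40 with quantile normalization, 9 with centring, 6 with trend and robust options and 3 with dim genes left out. The array weights, from 0.105 to 20.2, were not estimated to convergence, so counts under them rest on a few arrays. At a log2 change of 0.5 the model recovered 0% of simulated changes as deposited with redrawn residual arrays and 2.99% with independent noise, so small changes could be missed, as the 1911 calls after quantile normalization for 5 ng against 3 ng at 24 h also suggest. Except where the construction shows it (fewer arrays, fewer genes, an estimated correlation), the cause was not tested for the values that follow.

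Quantile normalization moved the called genes to 1911 for 5 ng against 3 ng at 24 h, 506 at 12 h, 2797 and 4742 for 3 ng and 5 ng at 12 h against 0 ng, 2943 and 3386 for 24 h against 12 h at 3 ng and 5 ng, and 13 for the interaction, and the called lists to 5 at each dose for 24 h against 12 h. Centring moved these counts to 946, 206, 3620 (3 ng at 12 h), 1246 (24 h against 12 h at 5 ng) and 1, and the lists to 5 (24 h against 12 h at 5 ng) and 4 (interaction). Array weights gave 1629, 9460, 8031, 7242, 3095, 7172 and 2643 genes in the order given for quantile normalization. For 5 ng against 3 ng at 12 h, the 4 calls became 0 with only the groups compared, 23 with dim genes left out, 2 with all transcript clusters and 32 with trend and robust options. For 3 ng at 12 h against 0 ng the counts were 232 with only the groups compared, 947 with dim genes left out and 1118 with trend and robust options, and the interaction had 1 gene with the latter. The correlation of the dose differences was 0.719 with dim genes left out, 0.222 over all transcript clusters, 0.254 with array weights and 0.782 over genes called against 0 ng only. With split controls the overlap of calls was 1925, 1577, 2089, 1488, 2204 and 2219.

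With an estimated correlation the called lists fell from 9, 12, 13, 11, 10, 12, 8, 8 and 8 to 0, 0, 1, 0, 0, 0, 3, 3 and 1, in the order 3 ng and 5 ng against 0 ng at 24 h, 5 ng against 3 ng at 24 h and 12 h, 3 ng and 5 ng at 12 h against 0 ng, 24 h against 12 h at 3 ng and 5 ng, and interaction. After quantile normalization the estimated correlation called 7, 7, 5, 4, 6, 7, 3, 4 and 3. These lists are given with each comparison in the results. The difference of medians of the arrest and apoptosis lists was 0.00625 at 3 ng and 0.0125 at 5 ng against 0 ng, with the other sign than the difference of means.

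With 1 array left out, the called genes ranged from 2782 to 5058 and from 3956 to 5324 for 3 ng and 5 ng against 0 ng at 24 h, 276 to 374 and 0 to 11 for the dose difference at 24 h and 12 h, 257 to 2782 and 1510 to 3086 for 3 ng and 5 ng at 12 h against 0 ng, 484 to 1395 and 506 to 811 for 24 h against 12 h at 3 ng and 5 ng, and 0 to 0 for the interaction. After quantile normalization they ranged, in the same order, from 4348 to 5302, 6326 to 6969, 1373 to 1748, 236 to 556, 2017 to 2869, 4074 to 4747, 2178 to 2949, 2651 to 3232 and 2 to 45. In that order the called lists ranged from 7 to 11, 11 to 14, 11 to 16, 10 to 14, 10 to 11, 11 to 12, 5 to 9, 4 to 11 and 5 to 12. The list counts moved by over 1.5 times for 24 h against 12 h at 3 ng without replicate 1 of 3 ng at 24 h (5), at 5 ng without replicates 3 (5) and 4 (4) of 5 ng at 12 h or replicate 2 of 5 ng at 24 h (5), and for the interaction without replicate 4 of 3 ng at 12 h, replicate 3 of 5 ng at 12 h, replicates 2 and 4 of 3 ng at 24 h, or replicate 2 of 5 ng at 24 h (5 each). The arrays that move gene counts this far are named with each comparison in the results. The overlap of calls ranged from 2571 to 4299, the correlation from 0.426 to 0.563, and the differences of arrest and apoptosis means from -0.20 to -0.17 and -0.14 to -0.10 between the doses at 24 h and 12 h, and from -0.29 to -0.26 and -0.47 to -0.45 at 3 ng and 5 ng against 0 ng.

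The values that changed sign all belong to genes that were not called as deposited, and BAX and TNFRSF10B at 3 ng and BBC3 and RAD51C at 5 ng, against 0 ng at 24 h, were called after quantile normalization. At 3 ng against 0 ng at 24 h these were BBC3 (0.20 after quantile normalization, 0.12 with centring), BAX (0.46, 0.22, and 0.15 with array weights), TNFRSF10B (0.38, 0.17 and 0.020) and, with 1 array left out, GADD45A (-0.049 to 0.21), BAX (-0.055 to 0.11) and TNFRSF10B (-0.16 to 0.043). At 5 ng against 0 ng at 24 h they were BBC3 (0.30, 0.25 and 0.10, and -0.092 to 0.085 with 1 array left out), RAD51C (0.21 after quantile normalization, 0.092 with centring) and PMAIP1 (-0.0042 to 0.23 with 1 left out). For 5 ng against 3 ng at 12 h they were BBC3 (0.056, 0.11 and 0.053, and -0.20 to 0.048), CCNB1 (0.12 with array weights) and CDK1 (0.17 with array weights, -0.35 to 0.022 with 1 left out). Against 0 ng, PMAIP1 at 3 ng and 12 h had 0.18 after quantile normalization and -0.17 to 0.068 with 1 left out, and BBC3 at 5 ng and 12 h -0.082 to 0.17. For 24 h against 12 h at 3 ng, centring gave CDKN1A 0.060, MDM2 0.16, GADD45A 0.20, BBC3 0.075 and BAX 0.043, quantile normalization GADD45A 0.060 and BBC3 0.072, and array weights MDM2 0.024, GADD45A 0.13 and BAX 0.069. At 5 ng, centring gave GADD45A 0.15, BBC3 0.10, PMAIP1 0.043, BAX 0.093 and TNFRSF10B 0.035, quantile normalization GADD45A 0.061, BBC3 0.12 and BAX 0.032, array weights BBC3 0.0036 and FAS -0.0051, and 1 array left out MDM2 -0.010 to 0.067, GADD45A -0.074 to 0.049, BBC3 -0.19 to 0.062 and FAS -0.044 to 0.053. For the interaction, centring gave GADD45A -0.043 and TP53I3 -0.078, quantile normalization TP53I3 -0.056, array weights GADD45A -0.16, BAX -0.16 and TP53I3 -0.13, and 1 array left out TP53I3 -0.018 to 0.13.

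The replicate numbers were checked for pairing. In no comparison did all 4 same-numbered pairs of arrays correlate above 0.1 in their deviations from the group means (from -0.179 to 0.501), and 3 to 5 of 8 arrays correlated best with their own number, so the numbers were not taken to pair the arrays. With the replicate block the called genes were 4796 and 5398 for 3 ng and 5 ng against 0 ng at 24 h, 495 and 2 for the dose difference at 24 h and 12 h, 702 and 3044 for the 12 h groups against 0 ng, 942 and 816 for the times and 0 for the interaction, and 4 of 361 named values lost their call, PMAIP1 for the dose difference at 24 h and PALMD, ARRB1 and FRMD8 for that at 12 h.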

Other observations

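The test of the LCE genes, and the lists of LCE and of Fanconi anemia and recombination genes, were chosen only after the data were seen, and the genes named here were chosen after their values were seen.

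Late cornified envelope genes, which encode proteins of the outer skin layers, moved unequally. LCE1B, LCE1C and LCE1F were among the largest rises and prompted the LCE1 list, which holds them. At 3 ng against 0 ng at 24 h, 5 of the 6 LCE1 genes rose (median log2 change 1.42) and 1 of the 11 other LCE genes did (median 0.06). At 5 ng all 6 rose (median 2.65), against 3 of 11 (median 0.07), and between the doses at 24 h 6 rose (median 1.10), against 2 of 11. Without the 3 genes that prompted the list, the medians of LCE1A, LCE1D and LCE1E were 0.55, 1.20 and 0.71 in these comparisons, and LCE1D (0.14) did not pass at 3 ng. LCE1C rose by 5.79, LCE1F by 3.76, LCE1A by 1.54, LCE1E by 1.20 and LCE1D by 0.85 at 5 ng (limma, 4 arrays in each group). After quantile normalization 6 of 6 and 6 of 11 rose at both doses.

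Genes of the Fanconi anemia pathway and of homologous recombination, which repair crosslinks and double-strand breaks, fell together. Of 16, all fell at 3 ng against 0 ng at 24 h (median -1.81) and 15 at 5 ng (median -2.19), and after quantile normalization 14 and 15 did. XRCC2 changed by -4.64 at 5 ng, FANCB by -3.98, BRIP1 by -3.69 and FANCI by -3.35, while RAD51C had -0.18 and did not pass (0.21, a rise past the threshold, after quantile normalization). Between the doses at 24 h 5 fell (median -0.45), and after quantile normalization 9 fell and 1 rose. Without XRCC2 and FANCC, which had been named before the list was drawn up, camera gave the other 14 adjusted p = 0.0275 and 0.0360 against 0 ng with an estimated correlation, and 0.0984 between the doses, over the 3 added lists. The list was drawn up from these same arrays, so leaving out those genes does not make the test independent. It sets the list against all other genes, and a fall apart from that of the S phase genes was not tested.

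One hypothesis is that the rise extends over the LCE1 genes more than over the rest of the LCE family. The 3 LCE1 genes that the rule had not named (LCE1A, LCE1D and LCE1E) changed by 1.20 ± 0.34 (SD) at 5 ng against 0 ng at 24 h and the 11 other LCE genes by 0.24 ± 0.46. A two-sided exact permutation test of membership over 364 arrangements gave p = 0.0137 (1.54 against 0.55 and exact p = 0.0110 after quantile normalization), so the means go with the hypothesis. Single genes did not all follow it. Of the 11 others, LCE3D (1.26) and LCE3E (0.94) rose by more than LCE1D (0.85), and the rest by less. LCE1 genes are near-identical copies, and probes of 1 may also bind transcripts of another, which these data cannot separate.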
